A study of Mus musculus with 10 samples.

How the data were processed

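Total RNA of sorted progenitor cells was made into sequencing libraries from 0.1 ug each with an Illumina TruSeq RNA kit, per the labels' protocols. Each of the 10 libraries was assigned to the naive, KDR-negative tumor or KDR-positive tumor group from its label. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, without their roles. The program that counted reads, the annotation and the program that tested the genes are not given in the sources used here.

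A single table was used. Per the file headers it gives, for each of 12791 gene names and each of 2 comparisons, a log fold change, a mean log CPM, a p-value and a false discovery rate. The log fold changes and mean levels of the authors are read as log2 values, since means derived from both under base 2 match between the comparisons (below). The p-values were deposited by the authors with their adjusted values, which equal the Benjamini-Hochberg adjustment recomputed here from the p-values. The CPM values deposited by the authors, summed over genes after undoing the log2, come to 1414420 in the first comparison and 732013 in the second, so they are not on one scale with a fixed total, and whether they were scaled to transcript length before the comparison is not given in the sources used here. The table has no value per library. For this reason the tests planned before the data were examined, which needed counts or normalized values per library, could not be run. Depth, replicate spread, pairs of libraries and other splits of the libraries could not be examined, and the authors' fold changes and p-values are used as they stand.

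The header names no groups. To learn which sides of the comparisons match, the level of each side was derived from the mean and the fold change, with weights for the group sizes. Over 9044 genes above 3 log2 CPM in both comparisons, the denominator levels of the 2 comparisons differed with a median absolute deviation of 0.0087 (log2) at equal weights, against 0.064 for the next pair of sides. The denominator groups of the 2 comparisons are therefore treated as the same group, and no overlap or correlation of their calls is given. The levels in CPM printed for single groups use the weights that fitted best, 0.48 for the numerator group of the first comparison and 0.59 for that of the second. On means simulated by the same formula with known weights the fit was off by at most 0.0014, less than its grid step of 0.01.

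A gene was called higher or lower at an adjusted p under 0.05. Genes named in the text follow a rule fixed before the data were examined. These are Kdr, Kit and Ly6a; the 8 largest fold changes in each direction among genes past the threshold with a mean of at least 4 CPM, leaving out predicted genes and clone names; and, for each list that passed or held at least 3 genes past the threshold, the 4 members with the smallest p. The rule set the mean over all 10 libraries, and the mean within the comparison was used instead. It also asked that libraries of the groups do not overlap, which could not be applied. Genes named beyond these, Cd22, Ccr2, F13a1, Ccl9, H2-Oa, H2-Ob, Rhag, Ank1, Id3, Plxna1, Itgb3, Flt1, Nrp1, Nrp2 and Thbs1, and those of the closing section, were chosen after their values were seen. Gene names follow the table, and 99.2% of them are a symbol or synonym of the RefSeq gene table of GRCm38. Among the names 19 had been turned into dates before deposit and were named nowhere in the text.

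Gene lists were fixed before the data were examined. They cover stem and multipotent progenitors, erythroid cells, heme biosynthesis, megakaryocytes, primary and late neutrophil granules, monocytes, macrophages and dendritic cells, myeloid suppressor genes, endothelial cells, T and NK cells, B cells, mast cells, basophils and eosinophils, stromal cells, brain and glioma, S phase, mitosis, interferon response, inflammatory genes, pro-angiogenic factors, VEGF receptors, lineage transcription factors, chemokine receptors and adhesion, immediate early genes, glycolysis and hypoxia, the unfolded protein response, cholesterol biosynthesis, ribosomal proteins, histones and class II antigen presentation. The list of mitochondrially encoded genes had fewer than 5 members in the table and was not tested. The 29 lists were tested in both comparisons with cameraPR (limma 3.58.1 in R 4.3.3), a competitive test of a list against all other genes, on z values that carry the authors' p-values with the sign of the fold change, at an inter-gene correlation of 0.01. On simulated z values, drawn independently for each gene, with real lists shifted by 1.5, 117 of 120 shifted lists and 1 of 327 unshifted lists passed. Of 580 simulated list tests in which a trend over level was the only effect, 83 passed before and 2 after the trend was removed. Neither simulation held correlated genes or z values distributed as in the second comparison. They therefore do not measure how often lists of co-expressed genes pass without a shift. A further 4 lists, of resident macrophages, lysosomes, paired immunoglobulin-like receptors and C-type lectin receptors, were drawn up after the data had been seen, both receptor lists holding genes already named for their fold changes, and are given as counts and medians without a list test. The trend over level and transcript length was removed from the z values by a local regression. Lengths are those of the longest transcript in GENCODE M21, found for 98.6% of the genes, and no coordinates are given because that annotation is of another build than mm8. The median of each list was also placed among 10000 random lists matched on denominator level and transcript length. These were drawn from all genes other than small RNA genes, the list's own members included. Of 100 simulated lists without an effect of their own 7 lay outside the central 95% of matched lists, and of 100 shifted by 1 on the log2 scale 84 did.

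The alternatives run were all chosen after the data had been seen, since those planned needed values per library. Counts of genes were recomputed at an adjusted p of 0.01, with a 2-fold minimum, over genes with a mean of at least 4 CPM, without small RNA genes (names starting with Snord, Snora, Scarna or Mir), with the Benjamini-Yekutieli adjustment and with fold changes centred on their median. The list test was repeated on ranks, on log2 fold changes, with a correlation of 0.05 and with the trend removed. Genes with near-identical copies, among them the globin, histone, Pira, Cd209 and ribosomal protein genes, can share reads and are uncertain as single genes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.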

Results

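RNA from hematopoietic progenitor cells of mouse bone marrow, sorted as lineage-negative, c-Kit-positive and Sca-1-negative cells from C57BL/6 mice, was measured by bulk RNA sequencing. The labels describe 10 libraries in 3 groups. These are 3 naive libraries from mice without a tumor, 4 KDR-negative libraries and 3 KDR-positive libraries, the last 2 groups from mice bearing GL261, a mouse glioma line, at week 4. KDR, a receptor of vascular endothelial growth factor, was followed through a GFP reporter knocked into its gene, and a GFP-positive sample came from about 20000 cells. No label says that libraries of a group came from separate mice, so the authors' p-values can speak only for these samples, whose spread may be technical. How that spread was estimated is not given in the sources used here. P-values of the list tests rest on the spread between genes at a preset correlation, and not on a spread between libraries.

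The authors' deposited table holds the results of 2 comparisons between groups over 12791 genes, each with a log2 fold change, a mean level in log2 CPM, as its header names the unit, a p-value and an adjusted p-value. It holds no value per library, so the depth of each library is unknown and no standard deviation stands beside the fold changes below. Its column names identify neither the groups compared nor the direction of the fold change. The 2 comparisons are therefore called the first and the second, in the order of the columns. The numerator group is the one in which a gene with a positive fold change is higher, and the other is the denominator group. Which of the questions set by the design each comparison answers, tumor against no tumor or KDR-positive against KDR-negative cells, is not stated in the sources used here.

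Kdr, the gene behind the sort, was low in both comparisons of the authors' deposited table, with a mean of 0.65 log2 CPM in the first and -0.84 in the second. Its log2 fold change there was 1.26 in the first comparison (adjusted p = 0.617) and -1.11 in the second (adjusted p = 1), so no difference was detectable in either. Kit, which encodes the c-Kit receptor of the sort, had log2 fold changes of -0.60 (adjusted p = 0.128) and 0.04 (adjusted p = 1) in the authors' deposited table. Ly6a, which encodes Sca-1, had 0.43 (adjusted p = 0.402) and -0.02 (adjusted p = 1) in the authors' deposited table.

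The first comparison separated the groups widely, and genes of platelets and of their precursors, the megakaryocytes, were among the most uniform. Of 22 measured genes of the megakaryocyte list, 21 were higher in the numerator group and none was lower, with a median log2 fold change of 2.77 (22 were higher adjusted over the list alone). In the authors' deposited table Pf4, the chemokine of platelet granules, had a log2 fold change of 3.43 (adjusted p = 3.8e-26), Treml1 3.16, Cd9 3.16 and Gp1bb, a subunit of the platelet receptor for von Willebrand factor, 3.63. Genes of mature myeloid cells moved apart. In the list of monocytes, macrophages and dendritic cells 16 of 30 genes were higher and 4 lower (17 and 5 adjusted over the list alone), with a median of 1.47. In the authors' deposited table Emr1, which encodes the macrophage surface protein F4/80, at 4.41 and Ctss at 2.87 were higher, while the monocyte chemokine receptors Cx3cr1 at -2.59 and Ccr2 at -1.20, F13a1 at -1.10 and Ccl9 at -1.05 were lower.

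B cell genes lay in the opposite direction. Of 19 measured B cell genes, 12 were lower in the numerator group and 1 was higher, with a median of -2.09 (13 lower and 1 higher adjusted over the list alone). Dntt, the polymerase that adds bases at antigen receptor joints, had a log2 fold change of -2.92 in the authors' deposited table (adjusted p = 1.1e-13), Igll1, a part of the surrogate light chain, -2.75 and Vpreb3 -1.95. The B cell gene that was higher, Cd22, stood at 2.02 in the authors' deposited table. Among 21 T and NK cell genes, 5 were lower and 2 higher (7 and 2 adjusted over the list alone), with a median of -2.51. The list did not pass its test (adjusted p = 0.070), though it did on log2 fold changes (3.3e-09) and on ranks (0.018). Klrd1, a receptor of natural killer cells, stood at -5.86 in the authors' deposited table, Gzmb at -3.90 and Lck at -2.55, while Lat, an adaptor of T cell receptor signalling that platelets also use, stood at 2.20. Klrd1 at 0.156 CPM and Gzmb at 0.581 CPM were near 0 in the numerator group, so the size of their fold changes is uncertain. Flt3, a receptor of early multipotent and lymphoid progenitors, was also lower in the authors' deposited table, at -2.28 (adjusted p = 5.6e-09). In the list of stem and multipotent progenitors as a whole 5 of 20 genes were lower and 3 higher, the same adjusted over the list alone, the higher ones including Mycn at 1.89 and Lmo2 at 1.36 in the authors' deposited table.

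Granule, antigen presentation and interferon genes were higher as well. In the list of late neutrophil granules 9 of 18 genes were higher and none lower, also adjusted over the list alone, with a median of 1.87. Lyz2, the lysozyme of myeloid cells, had a log2 fold change of 3.54 in the authors' deposited table (adjusted p = 3.4e-25), S100a8 2.29, S100a9 2.51 and Chi3l3 2.12. Of the 11 genes of class II antigen presentation 8 were higher and 2 lower, the same adjusted over the list alone, with a median of 1.87. H2-DMb2 and H2-DMb1, which help to load peptides on class II molecules, stood at 3.24 and 2.29 in the authors' deposited table, Ctss at 2.87 and the invariant chain gene Cd74 at 2.54, while H2-Oa and H2-Ob stood at -1.50 and -1.97. Ctss and Cd74 also belong to the list of monocytes, macrophages and dendritic cells. Markers of resident macrophages, a list drawn up after the data had been seen, were higher in the same group for 27 of 27 genes, with a median of 5.13, and in the second comparison had a median of -1.78, where class II genes had -0.34. Among 35 interferon response genes 15 were higher and 1 lower, the same adjusted over the list alone, with a median of 0.97. Ifit3 stood at 6.19 in the authors' deposited table (adjusted p = 6.1e-17), the antiviral enzyme gene Oas1a at 2.77, the transcription factor Irf7 at 2.01 and Rtp4 at 2.09.

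Replication-dependent histone genes, whose messages lack a poly(A) tail, were higher for 49 of 65 members and lower for none, with a median of 2.10 (53 higher and 1 lower adjusted over the list alone). Hist2h2aa1 stood at 3.30 in the authors' deposited table (adjusted p = 3.1e-21), Hist1h2bl at 3.24, Hist1h2bn at 3.19 and Hist1h2bf at 3.10. These genes have near-identical copies, so the split between single members is uncertain. The S phase list, by contrast, had a median of -0.02, with 8 of 43 genes higher, among them Pcna at 1.83 in the authors' deposited table, and 1 lower, also adjusted over the list alone. Genes of mitosis had a median of 0.00, with 10 of 50 higher and 2 lower, also adjusted over the list alone, among them Cks2 at 2.15 in the authors' deposited table.

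Ribosomal protein genes were higher for 76 of 80 members and lower for none, also adjusted over the list alone, with a median of 2.03. Rps21 stood at 2.36 and Rps15 at 2.35 in the authors' deposited table. Fold changes rose with the level of the gene from 3 log2 CPM on. In genes other than small RNA genes the median log2 fold change was -0.54 at a level of 3 to 4 log2 CPM in the denominator group, 0.11 at 5 to 6, 1.03 at 6 to 7 and 2.05 over 8. Random lists matched to the ribosomal protein genes on level and transcript length had a median of 2.03, and with the trend over level and length removed the list no longer passed (adjusted p = 0.571). Both controls kept the list's own genes. Only 199 genes other than small RNA genes lay over 8 log2 CPM in the denominator group, many of them ribosomal protein genes. These controls therefore cannot separate an effect of level from one of the ribosomal protein genes themselves. As with ribosomal proteins, 3 other lists passed only before the trend was removed. For primary neutrophil granules 9 of 16 genes were higher and 1 lower (9 and 3 adjusted over the list alone), led by Elane at 2.37, Mpo, the myeloperoxidase, at 2.40, Prtn3 at 2.34 and Ctsg at 2.03 in the authors' deposited table. For glycolysis and hypoxia 11 of 25 were higher and 1 lower (11 and 2 adjusted over the list alone), led by Ldha at 2.47, Aldoa at 2.21, Eno1 at 2.15 and Pgk1 at 2.08 in the authors' deposited table. For the unfolded protein response 10 of 21 were higher and 1 lower (11 and 2 adjusted over the list alone), led by Calr at 2.08, Pdia3 at 1.94, Hspa5 at 1.88 and Hsp90b1 at 1.78 in the authors' deposited table. With the trend removed their adjusted p-values were 0.859, 0.571 and 0.313. Removing the trend also brought lists past the test that had not passed before. These were lower for S phase (adjusted p = 0.0021), mast cells, basophils and eosinophils (0.018), erythroid genes (0.020, over 30 of 32 genes), T and NK cells (0.022) and mitosis (0.035). The 5 genes of VEGF receptors and co-receptors passed as higher (0.021), but only Itgb3 and Plxna1 among them were past the threshold, and Flt1, a receptor itself, lay below 0.

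**Figure D1:**
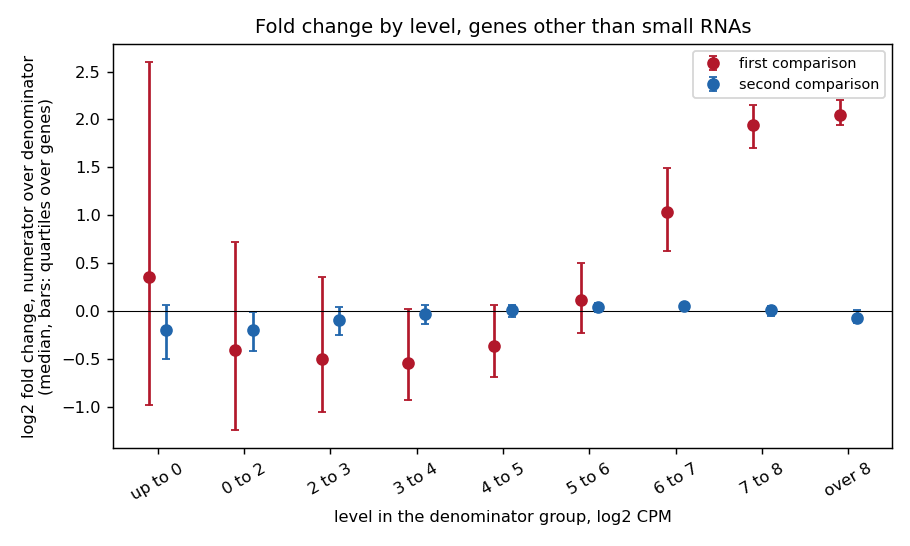
Median log2 fold change (points, with quartiles over genes as bars) by the level of the gene in the denominator group in log2 CPM, for genes other than small RNA genes, in the first (red) and the second (blue) comparison. In the first comparison the median goes from -0.54 at 3 to 4 log2 CPM to 2.05 over 8, and in the second it goes from -0.03 to -0.07 between the same classes.

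Erythroid genes went both ways, with 8 of 32 higher and 8 lower (9 and 10 adjusted over the list alone) and a median of -0.06. The 4 globin genes were higher, from 3.33 for Hbb-b1 to 4.89 for Hbb-b2 in the authors' deposited table, with Hba-a1 at 3.97 and Hba-a2 at 3.71. The 8 lower genes included those of the red cell surface and membrane skeleton, such as Rhag at -1.17 and Ank1 at -1.42 in the authors' deposited table. Genes of mast cells, basophils and eosinophils also split, with 4 of 21 higher and 5 lower, the same adjusted over the list alone. The eosinophil receptor gene Ccr3 stood at 5.75 in the authors' deposited table, Ear2 at 3.71 and Ear1 at 1.86, against -1.68 for the mast cell protease Cpa3.

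Among genes past the threshold with a mean of at least 4 CPM, predicted genes and clone names left out, the 8 with the largest positive fold change included the lectin receptor genes Cd209g, at 8.34 in the authors' deposited table (adjusted p = 1.4e-20), and Cd209f at 7.20, the myeloid receptor genes Cd300lh at 8.14 and Pira11 at 6.71, the ribonuclease gene Ear3 at 7.45 and the microRNA genes Mir1945 at 10.87, Mir1906-1 at 8.12 and Mir7-1 at 6.64. The 8 with the largest negative fold change were genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, led by Snord12 at -14.31 (adjusted p = 2.8e-88), Snord57 at -14.02 and Snord37 at -13.95 in the authors' deposited table. Of 141 snoRNA, scaRNA and microRNA genes 69 were lower and 11 higher. They made up 52 of the 53 genes that lay under 0.2 CPM in the numerator group and at 20 CPM or more in the denominator group, and the fold change of such a gene depends on the prior count of the fit and is no bound. The same holds for genes near 0 in the denominator group, such as Cd300lh at 0.138 CPM and Mir1945 and Mir1906-1 at 0.12 CPM there, whose place among the largest fold changes rests on it.

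**Figure D2:**
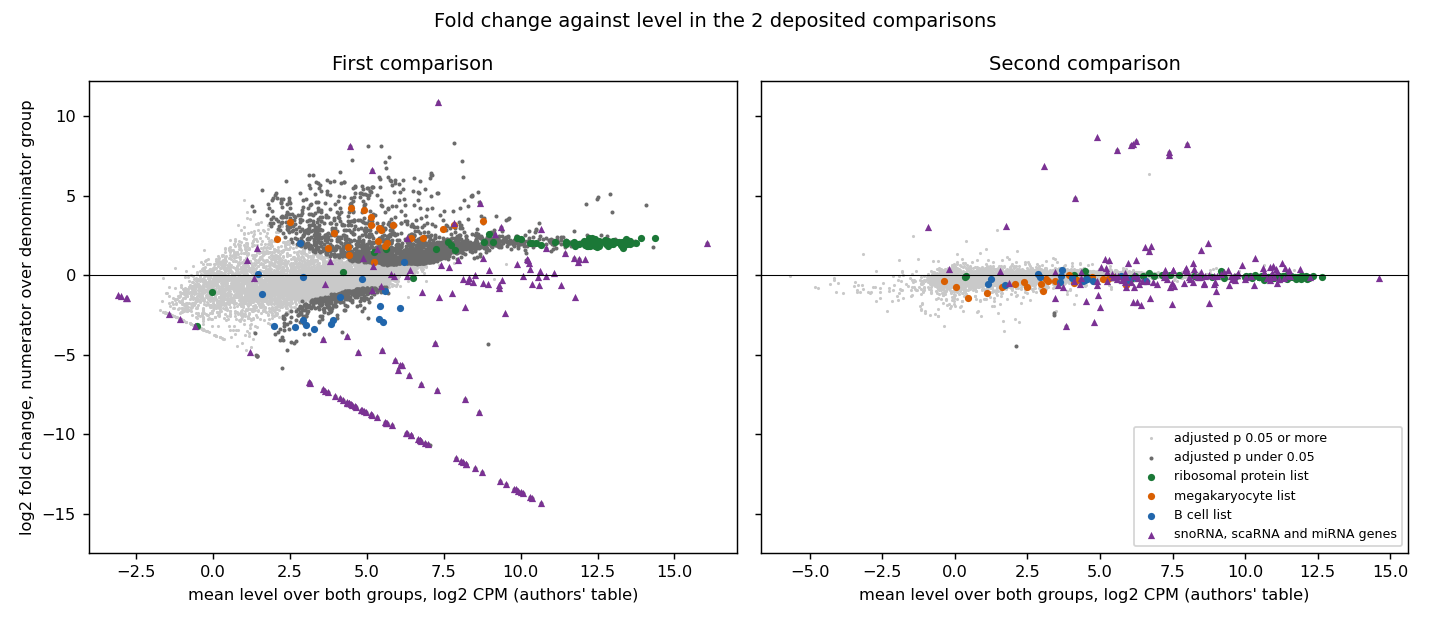
Log2 fold change (numerator over denominator group) against the mean level in log2 CPM for each gene of the first (left) and the second (right) comparison, as deposited. Dark grey points have an adjusted p under 0.05, and colours mark the ribosomal protein, megakaryocyte and B cell lists and the small RNA genes. In the left panel 76 of 80 ribosomal protein genes and 21 of 22 megakaryocyte genes are higher, and 69 of 141 small RNA genes are lower, most of them along a line set by their absence from the numerator group.

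Lists of other cell types and programs did not pass the list test in the first comparison. For endothelial cells 4 of 15 measured genes were higher and 1 lower, with Fabp4 at 5.39, Esam at 1.69 and Tie1 at 1.17 in the authors' deposited table. The median of the endothelial list was -0.44, so the higher genes do not stand for the list. Of the VEGF receptor and co-receptor list, which leaves out Kdr, 2 of 5 genes were higher, Itgb3 at 2.86 and Plxna1 at 2.51 in the authors' deposited table, while Nrp1 at 0.44, Nrp2 at 0.47 and the receptor kinase gene Flt1 at -2.11 (adjusted p = 0.728) did not pass. Itgb3 also belongs to the megakaryocyte list. For pro-angiogenic factors 5 of 15 were higher and none lower, with Ang at 3.20 in the authors' deposited table beside S100a8 and S100a9. Myeloid suppressor genes were higher for 6 of 15, among them the oxidase subunit gene Cyba at 2.28 in the authors' deposited table. Inflammatory genes were higher for 6 of 22, with Il1b at 3.98 and Il1a at 3.97 in the authors' deposited table and 1 gene, Ccl3, lower at -2.10. Among Id proteins and lineage transcription factors 5 of 30 were higher and 4 lower, with Id2 at 2.24 (adjusted p = 9.1e-09) and Id3 at -3.44, Runx2 at -2.31 and Ets1 at -1.80 in the authors' deposited table. Chemokine receptor and adhesion genes were higher for 6 of 26 and lower for 5, with the integrins Itgb2 at 2.13 and Itgal at -1.42 and the selectin ligand Selplg at 1.17 in the authors' deposited table. Immediate early and dissociation stress genes were higher for 10 of 22 and lower for 1, with the heat shock genes Hspa8 at 2.29, Hspa1a at 3.33 and Hspa1b at 3.14 in the authors' deposited table. For stromal cells 1 of 7 was higher and 2 lower, for brain and glioma 1 of 6 higher, for heme biosynthesis 2 of 12 higher and for cholesterol biosynthesis 2 of 21 higher, with none lower in the last 3. Adjusted over the list alone, these counts changed to 2 lower for endothelial and for immediate early genes, and to 7 higher for inflammatory and for chemokine receptor and adhesion genes, and stayed as they were for the other lists of this paragraph. The median, the mean and the test did not all have 1 sign for the erythroid, endothelial, brain and glioma, S phase, mitosis, heme biosynthesis and lineage transcription factor lists, none of which passed before the trend was removed.

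In all, 2847 genes of the authors' deposited table (22.3%) had an adjusted p under 0.05 in the first comparison, 2401 higher and 446 lower, and 3936 had an unadjusted p under 0.05. Directions are relative to the deposited scale. CPM values summed to 1414420 in the first comparison and 732013 in the second, which implies a larger total in the first numerator group. Equal totals would lower all fold changes of the first comparison alike, and counts and list medians at equal totals were not computed. The competitive list test (limma's cameraPR on signed z values from the authors' p-values, two-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over 58 tests) passed 11 of the 29 lists. The smallest adjusted p-values were 1.1e-48 for ribosomal proteins, 7.1e-26 for histones, 1.8e-23 for megakaryocytes, 1.1e-06 for B cells and 0.00043 for monocytes, macrophages and dendritic cells. The others that passed were interferon response (0.0018), late granules (0.0019), class II antigen presentation (0.0024), glycolysis and hypoxia (0.0050), primary granules (0.0051) and the unfolded protein response (0.0077). With ranks in place of z values the monocyte, macrophage and dendritic list did not pass (adjusted p = 0.053), and with a correlation of 0.05 glycolysis and hypoxia (0.056) and the unfolded protein response (0.060) did not. A correlation between genes could not be estimated, because that needs values per library.

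**Figure D3:**
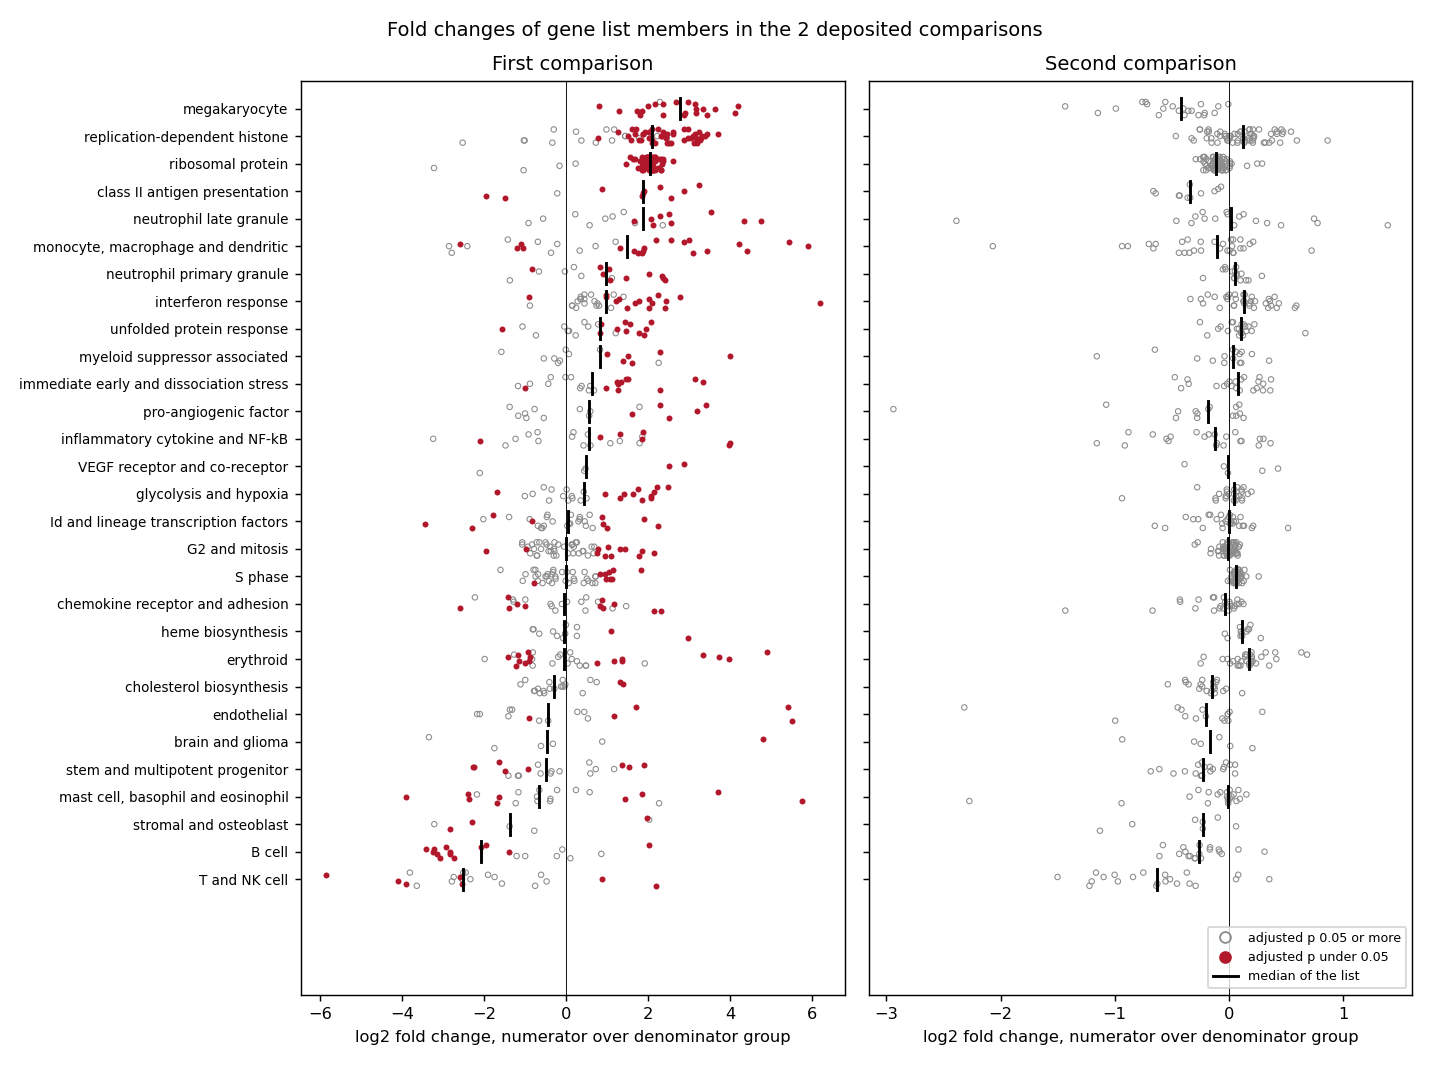
Log2 fold change (numerator over denominator group) of each measured member of the 29 gene lists in the first (left) and the second (right) comparison, on separate scales. Red points have an adjusted p under 0.05, open points do not, and black bars are the medians of the lists. In the left panel the megakaryocyte list has its median at 2.77 and the B cell list at -2.09, and in the right panel no member of any list is past the threshold.

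Few genes passed in the second comparison, and most of these were small RNA genes. The complement gene C1qa and the lectin gene Fcna were lower in its numerator group, C1qa at a log2 fold change of -2.41 (adjusted p = 0.020) and Fcna at -2.51 (adjusted p = 0.037) in the authors' deposited table. Acat3, an acetyl-CoA acetyltransferase gene, stood at -4.44 (adjusted p = 0.013) and Snord15a at -3.18 (adjusted p = 0.0049) in the authors' deposited table. In the first comparison of the authors' deposited table Acat3 was lower too, at -4.74 (adjusted p = 0.00026). Its level was 9.80 CPM in the shared denominator group and near 0 in both numerator groups, at 0.366 CPM in the first and 0.453 CPM in the second. Eef1a1, which encodes the elongation factor that brings tRNA to the ribosome, had a fitted log2 fold change of -16.12 (adjusted p = 4.3e-143) in the authors' deposited table, the level being 9404 CPM in the denominator group and 0.132 CPM in the numerator group, where a value is set by the prior count. In the first comparison of the authors' deposited table Eef1a1 stood at 1.80. Whether the RNA of Eef1a1 or the counting of its reads differed in the second comparison was not tested. Among genes past the threshold with a mean of at least 4 CPM, the 8 largest positive fold changes were those of the small RNA genes Mir5132 at 8.46, Mir707 and Mir451 at 8.27, Mir664, Mir196b at 7.88, Mir343 at 7.72, Mir5133 at 7.53 and Snora15 at 4.84 in the authors' deposited table. Several of these were near 0 in the denominator group, such as Mir5132 at 0.362 CPM and Mir196b at 0.348 CPM, so their fold changes and order depend on the prior count.

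As a whole 14 genes of the authors' deposited table passed in the second comparison, 9 higher and 5 lower. An unadjusted p under 0.05 was given for 43 genes, where 639.6 would follow from uniform p-values, and 95.4% of the p-values were over 0.5. The p-values were thus larger than groups without any difference would give, so the authors' test was conservative here. The small number of calls therefore does not show that the groups were alike. When small RNA genes were left out and p-values readjusted, 1 gene passed, Eef1a1, and C1qa, Fcna and Acat3 did not. No member of the 29 lists was past the threshold among all genes, and of their 694 genes 2 had an unadjusted p under 0.05. Thbs1, which encodes the matrix protein thrombospondin and is best known as an inhibitor of angiogenesis, was placed in the list of pro-angiogenic factors beforehand. It passed adjusted over that list alone, with a log2 fold change of -2.94 in the authors' deposited table (unadjusted p = 0.0013, adjusted p = 0.704 over all genes).

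Small shifts of whole lists were measured in the second comparison by the same cameraPR test, whose p-values do not tell whether a shift recurs between libraries. The megakaryocyte list lay below 0 for all 22 genes, with a median of -0.42 (adjusted p = 6.4e-09), Pf4 standing at -0.61 and Treml1 at -0.99 in the authors' deposited table. The T and NK cell list had a median of -0.63 (adjusted p = 5.0e-07), the class II list -0.34 (2.0e-06), the B cell list -0.26 (0.00011) and cholesterol biosynthesis -0.15 (0.00044). The erythroid list had a median of 0.18 (adjusted p = 2.1e-07), with 28 of 32 genes above 0. Ribosomal proteins had a median of -0.11 (adjusted p = 2.7e-06), which was not past the threshold with the trend over level and length removed (adjusted p = 0.541). The S phase list had a median of 0.07 and the interferon response list 0.14 (adjusted p = 0.012 for both). With the trend removed the S phase list did not pass (adjusted p = 0.070). The medians were 0.11 for heme biosynthesis (0.021), -0.22 for stem and multipotent progenitors (0.022), 0.13 for histones (0.030) and -0.10 for monocytes, macrophages and dendritic cells (0.046). The pro-angiogenic list, which holds Thbs1, had a median of -0.18 (adjusted p = 0.028, and 0.281 on ranks). Of these 14 lists 3 passed under every setting of the list test that was tried, namely megakaryocytes, T and NK cells and erythroid genes. The other 15 lists did not pass, and their medians ranged from -0.23 for stromal genes to 0.11 for the unfolded protein response. Median, mean and test did not all have 1 sign for glycolysis and hypoxia, lineage transcription factors, myeloid suppressor genes and VEGF receptors, all among these 15.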

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

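Every alternative reported here was chosen after the data had been seen. No paired analysis was possible because the table holds no values per library. For the same reason the alternatives set out before the data were seen were not run, namely other normalizations, tests, filters and pseudocounts, fits over 2 groups, a block by replicate number, leaving out single libraries, and list tests with an estimated correlation or by fry. Depth is unknown, so how far it limits low genes such as Kdr cannot be stated.

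In the first comparison the 2401 higher genes stayed within 1.5 times their number under 5 alternatives. The 446 lower genes came to 233 at an adjusted p of 0.01 and 186 with the Benjamini-Yekutieli adjustment, both stricter by construction. Centring on the median log2 fold change of -0.13 is no test of the calls, since it leaves p-values as they are and the smallest called fold change was 0.67. In the second comparison the 5 lower genes came to 2 at an adjusted p of 0.01 and 2 with Benjamini-Yekutieli. Without small RNA genes 0 were higher and 1 was lower, 1 past the threshold in all, all 9 higher genes being small RNA genes. The named genes that reach 4 CPM kept their side of the threshold when p-values were readjusted over such genes.

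Among the list tests 6 lists of the first comparison and 3 of the second passed under every setting. With the trend over level and length removed, the direction turned for ribosomal proteins of the first comparison (adjusted p = 0.571, then lower) and for erythroid genes (adjusted p = 0.020, then lower). Genes without a transcript length were left out there, so the erythroid test held 30 genes where the main test held 32. The turn of the erythroid list is therefore not on the same members. The same setting brought 5 further lists of the first comparison past the test, S phase, mitosis, T and NK cells and mast cells as lower and the VEGF receptor and co-receptor list as higher. Of the last list only Itgb3 and Plxna1 were past the threshold. At a correlation of 0.05, 2 lists of the first and 7 of the second comparison no longer passed, and on log2 fold changes 3 and 8 did not. Lists also came to pass, in the first comparison T and NK cells on log2 fold changes (adjusted p = 3.3e-09) and ranks (0.018) and immediate early genes on ranks (0.035), and in the second endothelial genes on log2 fold changes (0.027) and, on ranks, the unfolded protein response (0.00084), primary granules (0.0075) and stromal genes (0.039). The causes were not tested.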

Other observations

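Every test in this part except the slope over ribosomal protein genes was chosen after the values had been seen, and the macrophage, lysosome and receptor lists were drawn up then from textbook markers.

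No p-value is given for these lists, since the values that prompted them would be tested again. In the first comparison 27 of 27 measured genes of resident tissue macrophages were higher in the numerator group, with a median log2 fold change of 5.13, and in the second 2 were lower (6 adjusted over the list alone), with a median of -1.78. Fcna, a ficolin, was at 777 CPM in the first numerator group, 20.6 in the shared denominator group and 3.61 in the second numerator group. The complement gene C1qa was at 660, 20.6 and 3.89 CPM, Apoe at 807, 83.3 and 77.3, and Hmox1, which breaks down heme, at 603 and 8.50 in the 2 numerator groups. The macrophage lineage factor Spic was at 173, 4.35 and 1.11 CPM. These levels are on the deposited scale, whose total differs between groups. Of the 27 genes 5 also belong to the lists fixed beforehand, and 17 were at 4 CPM or more in the denominator group.

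Receptor families of myeloid cells went with them in the first comparison. All 9 measured genes of paired immunoglobulin-like receptors and their relatives were higher, with a median of 5.88 and 3 of them at 4 CPM or more in the denominator group, the authors' deposited table giving 6.41 for Pira2 and 6.15 for Pilrb1. Of 15 C-type lectin receptor genes 9 were higher and none lower (10 higher adjusted over the list alone), with a median of 1.63, Clec4a3 standing at 5.98 and Clec4n at 5.09 in the authors' deposited table. Neither family had a gene past the threshold in the second comparison, also adjusted over the list alone, where their medians were -0.50 and -0.33, and no gene of either had an unadjusted p under 0.05. Of 24 lysosomal genes 17 were higher and none lower in the first comparison, also adjusted over the list alone, with a median of 1.71, and in the second the median was 0.03.

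For the macrophage genes, random lists matched on level and length had medians between -0.62 and 0.23 against the observed 5.13. That is no test of the trend, since the list was drawn up after its values were seen. The monocyte, macrophage and dendritic list fixed beforehand had 1.47 against -0.26 to 0.48, which argues against the trend as the whole cause for that list. A smaller share of the main cell type would raise genes of all other cell types alike. The B cell list had a median of -2.09 against -0.51 to 0.56 in matched lists. Whether its genes came from other cells or from the sorted progenitors themselves is unknown, so this list cannot decide the question. Macrophage RNA or cells in the numerator group may account for the pattern. Lysosomal genes, none of them in the macrophage list, had a median of 1.71 where matched lists reached 0.73, as such RNA would need. Ctsb stood at 3.13 and Psap at 3.59 in the authors' deposited table. The lysosome list was also drawn up after the values were seen, so it is no test of macrophage RNA either. The lineage-negative, c-Kit-positive gate is meant to leave mature macrophages out, and whether the RNA came from passing cells, from attached fragments or from progenitors that express these genes in 1 of the study's groups was not tested.

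Many small RNA genes were near 0 in the first numerator group and abundant in the denominator group, and no biological explanation was tested. Scaling of the values to transcript length, which inflates very short genes, may play a part, but the slope of log2 level on log2 length over 80 ribosomal protein genes was -0.15 (bootstrap 95% interval -0.84 to 0.60), where reads would give about 1 and length-scaled values about 0. That interval lies under 1 but reaches over the bound of 0.25 set beforehand, and with coding length in place of transcript length the slope was -0.11 (-1.42 to 1.26), which includes both, so this stays undecided. Reads counted to host genes in that group would raise the hosts by a median of 1.36 if values were read-based and by 0.069 if they were length-scaled. The 43 host genes lay 0.093 above the trend (interval -0.18 to 0.25), so counting to hosts and loss of the RNA in the preparation cannot be told apart until the unit is known.

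The dependence of the fold change on level in the first comparison is argued against as an effect of transcript length alone, since within 2000 to 3000 nt the medians at over 7 and at 3 to 4 log2 CPM differed by 2.41. Fold changes also fell with length. At 3 to 4 log2 CPM the median was 0.40 for transcripts up to 1000 nt and -0.71 for those over 5000 nt. A single scaling factor is argued against by the difference of 2.59 between the medians at over 8 and at 3 to 4 log2 CPM, with quartiles that did not overlap. Library preparation, RNA amount and the biology of the groups stay open and were not tested.

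As a hypothesis on which groups were compared, weights of 3 libraries in the denominator group, 3 in the first numerator and 4 in the second gave the closest match of the denominator levels, with a median absolute deviation of 0.0066 (log2) against 0.031 for the next assignment of sizes. These sizes set weights of 0.50 and 0.57, while the weights that fitted best were 0.48 and 0.59, with a deviation of 0.0020. The sizes therefore do not match the fit exactly. An assignment of 3, 3 and 4 libraries would make the KDR-negative libraries the second numerator group. The denominator may then be the naive group, with the KDR-positive libraries as the first numerator, or the reverse. Kdr could have decided between them, but its adjusted p in the first comparison was 0.617, so the data do not tell.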
